A study of Mus musculus with 24 samples.

How the data were processed

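Retinal RNA of C57Bl/6 mouse pups was measured on 24 oligonucleotide arrays, 1 array per sample. Per the labels, the arrays fall into 8 groups of 3: pups in room air at postnatal days 7, 8, 10 and 12, and pups of the same ages exposed to hyperoxia for 12, 24, 72 and 120 hours. Age and duration of exposure therefore change together and cannot be told apart. The labels do not give the oxygen concentration, the time of day, the number of animals per array or the dissection protocol. They do not say whether replicates came from separate animals. From a common start, 12 and 120 hours of hyperoxia would end at different times of day, so days 7 and 12 may differ in it. The p-values measure only the spread between these samples, which may be technical.

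The deposited table holds 1 linear intensity per probe set and array for 22690 probe sets, of which 64 are control probe sets. The software and scaling the authors used are not given in the sources used here. After trimming 2% of the values at each end, the array means lay between 1500.35 and 1500.4, so the deposited intensities had been scaled by the authors to a common trimmed mean. The array medians still spanned 0.253 on the log2 scale. The scanner files and the spread of the single probes were not analysed here. The precision is limited by the number of arrays.

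The following choices were made before the data were examined: the groups, the tests, the named-gene rule, the gene lists, the floor, the filter and the alternatives to them. Intensities were taken to log2. Because the medians spanned more than 0.1, the arrays were quantile normalized, with the deposited scaling as an alternative. Values under the 20th percentile of the table, a signal of 135.6, were raised to it. Control probe sets were left out, and probe sets whose mean over the 24 arrays lay under the 30th percentile of all means were removed. This left 15838 probe sets, in which 0.34% of the values were at the floor. Differences near the floor are understated.

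Probe sets were named through the platform annotation supplied with the series: 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none. Of the first, 20364 were found by gene identifier in a current gene table, and 0 symbols had to be updated. Probe sets with several symbols or none were tested and counted but not named. The tested probe sets with 1 symbol numbered 14631 and stood for 9266 genes.

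Each comparison was a contrast of group means in one limma fit (version 3.58.1, R 4.3.3) over all 24 arrays, with 16 residual degrees of freedom and 3.54 prior degrees of freedom. The comparisons were hyperoxia against room air at each of the 4 ages and averaged over them, day 12 against day 7 in each condition, the hyperoxia effect at day 12 minus that at day 7, and an F test of any difference in the hyperoxia effect among the days. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are given as log2 hyperoxia minus room air, or day 12 minus day 7, with the standard error of the fit and 3 arrays per group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

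Of 37 gene lists, 35 had at least 5 measured genes and were tested with limma's camera, using a preset correlation between genes of 0.01 and 1 probe set per gene, the brightest. The red blood cell and skeletal muscle lists had fewer and were not tested. The adjustment was over the lists within a comparison, and each call was repeated with a correlation estimated from the data. Lists overlap: the 32 measured targets of hypoxia-inducible factor (HIF) and the 15 measured glycolysis genes share 9 genes, and 14 of the 16 measured tip cell genes stand in another list. A member of a list rose or fell where its adjusted p over all probe sets was under 0.05. Counts adjusted over the list alone are given beside it.

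Genes were named by rule. In each comparison except the F test and day 12 against day 7 in hyperoxia, these were the 10 largest rises and the 10 largest falls among called probe sets whose groups of arrays did not overlap. For the average over the days, the difference had to point the same way at every day. Each gene counted once, by its probe set with the lowest p. Up to 4 members with the lowest p were named from each called list, and in every comparison from the lists of HIF targets, endothelial cells, reactive gliosis, antioxidant genes and angiogenic factors. Where fewer than 5 probe sets were called, the 5 with the lowest p were named. Other genes named in the text were chosen after their values were seen.

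The procedure was tested on simulated data built on the arrays' own means and spread, with 200 of 15838 probe sets changed, 50 of them at each size. For the day 7 comparison it recovered 38% of the changes of 1.5-fold, 78% of 2-fold, 94% of 3-fold and 100% of 4-fold, with 9 false calls. For day 10 the shares were 30%, 88%, 96% and 100%, with 4 false calls, and for day 12 they were 46%, 80%, 100% and 100%, with 13 false calls, the most of the comparisons simulated. Of 200 simulated unchanged lists in the day 7 comparison, 2 had p under 0.05 in camera, and 200 of 200 lists lowered by 0.3 did. The simulated noise was independent between genes and the lists were drawn at random. The simulation therefore does not test the preset correlation on lists whose genes vary together.

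Replicates correlated with r of 0.946 to 0.985 across probe sets, and 0 pairs of columns were identical. Groups share replicate numbers. At day 12 the deviations from the group means correlated between same-numbered hyperoxia and room air arrays (r = 0.445, 0.234 and 0.39 across probe sets), and between day 12 and day 7 under hyperoxia they did so with r of 0.369, 0.151 and 0.305. All of these exceed 0.1, so the numbers were taken to pair the arrays there, on the evidence of the data and not of the labels. In the other comparisons the same-numbered pairs did not all exceed 0.1, and no pairing was taken there. Across groups, the mean correlation of the deviations was 0.0865 for arrays of the same number and -0.0431 for other numbers. A weaker sharing by number in all groups therefore stays open, and the main fit does not model it.

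The alternatives were the deposited scaling, floors at the 10th and 40th percentiles, no filter or a filter at the 50th percentile, the replicate number as a block, an intensity trend with a robust prior, 1 probe set per gene, only the groups compared in the fit, and leaving out each array in turn. For the lists, the mean of all probe sets of a gene was a further one. Added after seeing the data were the mean log2 signals of the lens and pigment lists per array (the lens and pigment scores) as covariates, the removal of the 2 arrays farthest from their groups, and list means per array tested on their own. All 24 columns of the table were used.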

Results

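The series follows the retina of C57Bl/6 mouse pups over 5 days of postnatal development in room air and in hyperoxia. Retinal RNA was profiled at postnatal days 7, 8, 10 and 12 in room air and, at the same ages, after 12, 24, 72 and 120 hours of hyperoxia, with 3 arrays in each of 8 groups. The median deposited intensity of an array ranged from 570.2 to 679.7. Raised oxygen at this age is used in the mouse to interrupt growth of the retinal vessels. The gene groups of main interest were therefore the targets of HIF, the transcription factor that mediates the response to low oxygen, and the genes of vessels.

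At day 7, after 12 hours of hyperoxia, genes of anaerobic metabolism and the vessel growth factor Vegfa were lower. Pdk1, a kinase that inhibits the mitochondrial pyruvate dehydrogenase, fell by 1.16 ± 0.18 on the log2 scale (adjusted p = 0.00827). Its mean went from 9.46 ± 0.22 to 8.30 ± 0.09 (SD, n = 3). Slc16a3, a lactate exporter, fell by 1.06 ± 0.18 (adjusted p = 0.0236), Ak4, a mitochondrial adenylate kinase, by 0.97 ± 0.15 (adjusted p = 0.00827), and Vegfa by 0.88 ± 0.13 (adjusted p = 0.0077). Grhpr, a glyoxylate reductase, Bnip3, a mitochondrial protein of mitophagy, and the glycolytic enzymes Pfkl, Tpi1 and Pgam1 fell by 0.57 to 0.87. These 9 genes were all the named genes among the 10 probe sets called, of which 0 were higher and 10 lower. Other probe sets of Tpi1 were at -0.38 ± 0.12 and -0.40 ± 0.12 and did not pass.

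Among the gene lists at day 7, 4 of 32 measured HIF targets fell (Vegfa, Pfkl, Bnip3 and Slc16a3), 11 when adjusted over the list alone, and 27 of 32 had negative differences. Pdk1 and Tpi1 also stand in this list. They count there by their brightest probe sets, as in all list counts, and these did not pass at day 7. The list mean was -0.31 (camera adjusted p = 1.45e-24). Of 15 glycolysis genes, 2 fell (Pgam1 and Pfkl), 6 when adjusted over the list alone (list mean -0.24, adjusted p = 4.65e-14). Both calls held with an estimated correlation, at adjusted p of 0.000157 and 0.0086. Among 25 angiogenic factors and receptors 1 fell, Vegfa, both over all probe sets and adjusted over the list alone (list mean -0.11, adjusted p = 0.00322; adjusted p = 0.156 with an estimated correlation). Members of this list that did not pass included Thbs1, an inhibitor of vessel growth, at -0.87 ± 0.31. In the endothelial list 0 of 24 genes passed and 20 had negative differences, among them Sox17 at -0.62 ± 0.19 and Cd34 at -0.50 ± 0.19 (list mean -0.19, adjusted p = 3e-06; adjusted p = 0.294 with an estimated correlation). The basement membrane list (mean -0.22, adjusted p = 0.000738; adjusted p = 0.114 with an estimated correlation), the tip cell list (mean -0.14, adjusted p = 0.00984; adjusted p = 0.188 with an estimated correlation) and the Müller glia list (mean -0.12, adjusted p = 0.000738; adjusted p = 0.188 with an estimated correlation) were also lower, with 0 members passing in each. The list of pigment epithelium and melanocyte genes, a neighbouring tissue, had a mean of -0.48 (adjusted p = 0.000425; adjusted p = 0.537 with an estimated correlation), with Ttr at -1.09 ± 0.44 and Rpe65 at -0.85 ± 0.45. With the pigment score as a covariate, the calls of the Müller glia, tip cell, basement membrane and angiogenic lists ended (adjusted p = 0.0887 for each). The tip cell call also ended without replicate 1 or 2 in all groups (adjusted p = 0.0714 and 0.193), and the angiogenic call without replicate 2 (adjusted p = 0.244).

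The limma test over all 8 groups gave the 10 calls at day 7 from 503 probe sets at an unadjusted p under 0.05, where 792 would be expected without any change. The count was 1 without hyperoxia replicate 3, 4 without room air replicate 3, 5 without room air replicate 2 and 6 without hyperoxia replicate 2. With only the 6 arrays of day 7 in the fit, limma called 0, with 472 probe sets at an unadjusted p under 0.05, and with a robust, intensity-dependent prior it called 17.

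At day 8, after 24 hours of hyperoxia, the same genes were lower. Pdk1 fell by 1.31 ± 0.18 (adjusted p = 0.00174), Ak4 by 1.22 ± 0.17 (adjusted p = 0.00174), and Bnip3 and Vegfa by 1.04 ± 0.12 and 1.04 ± 0.13 (adjusted p = 0.000794 for both). Slc16a3, Grhpr, Tpi1, Pfkl and Pfkp, the last a further phosphofructokinase of glycolysis, fell by 0.77 to 1.05. Cox4i2, an oxygen-responsive subunit of cytochrome c oxidase, fell by 1.14 ± 0.21 and Mag, a myelin glycoprotein, by 1.11 ± 0.21 (adjusted p = 0.0448 for both). Of 13 probe sets called, 0 were higher and 13 lower. All 10 probe sets called at day 7 were among them, against 0.00821 expected for independent lists, and the comparisons share no array.

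Of the HIF targets, 5 of 32 fell at day 8 and 12 did when adjusted over the list alone. The list mean was -0.38 (adjusted p = 2.86e-20, or adjusted p = 0.000492 with an estimated correlation). The brightest probe sets of Pdk1 and Tpi1, by which these genes count in the lists, again did not pass. In the glycolysis list 3 of 15 fell, Pfkl, Pfkp and Pgam1, and 4 adjusted over the list alone (list mean -0.30, adjusted p = 6.85e-12; adjusted p = 0.0182 with an estimated correlation). Vessel lists were lower without any member passing over all probe sets. The endothelial list had 2 members adjusted over the list alone and 18 of 24 negative differences, led by Cldn5, a tight junction protein, at -0.69 ± 0.19 (list mean -0.27, adjusted p = 1.7e-06; adjusted p = 0.355 with an estimated correlation). The pericyte and smooth muscle list was led by Rgs5 at -0.57 ± 0.15 (list mean -0.26, adjusted p = 0.00317; adjusted p = 0.31 with an estimated correlation). The tip cell list had a mean of -0.24 (adjusted p = 0.00242; adjusted p = 0.167 with an estimated correlation).

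Day 8 was also the day on which camera called the lens list. Its mean was -2.64 (adjusted p = 2.96e-06; adjusted p = 0.516 with an estimated correlation), all 16 measured members were negative, and none passed, with Crygd at -4.34 ± 2.1. The pigment list had a mean of -0.35 (adjusted p = 0.0439; adjusted p = 0.745 with an estimated correlation). The lens scores were 12.97, 10.87 and 8.81 on the room air arrays and 8.83, 8.12 and 7.80 on the hyperoxia arrays. With both the lens and pigment scores as covariates, the number of called probe sets was 8, and the pericyte and tip cell list calls ended (adjusted p = 0.0926 and 0.0616), with means of -0.20 and -0.18.

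The 13 calls at day 8 fell to 8 without hyperoxia replicate 1 and to 7 without room air replicate 2, and limma called 0 with only the 6 arrays of day 8 in the fit, with 720 at an unadjusted p under 0.05. Without replicate 1 in all groups the pericyte call ended (adjusted p = 0.0851), without replicate 2 the tip cell call did (adjusted p = 0.246), and the pigment call ended without any of the 3 (adjusted p = 0.175, 0.13 and 0.0629). The pigment call also ended without a filter (mean -0.32, adjusted p = 0.0685), with the lens score as a covariate (mean -0.40, adjusted p = 0.0888) and without the 2 arrays farthest from their groups (adjusted p = 0.15), where the pericyte call ended as well (adjusted p = 0.103). The angiogenic list was called at day 8 only with the mean of all probe sets of a gene (adjusted p = 0.00799), on the deposited scaling (adjusted p = 0.0153) and with the replicate block (adjusted p = 0.0489).

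**Figure D1:**
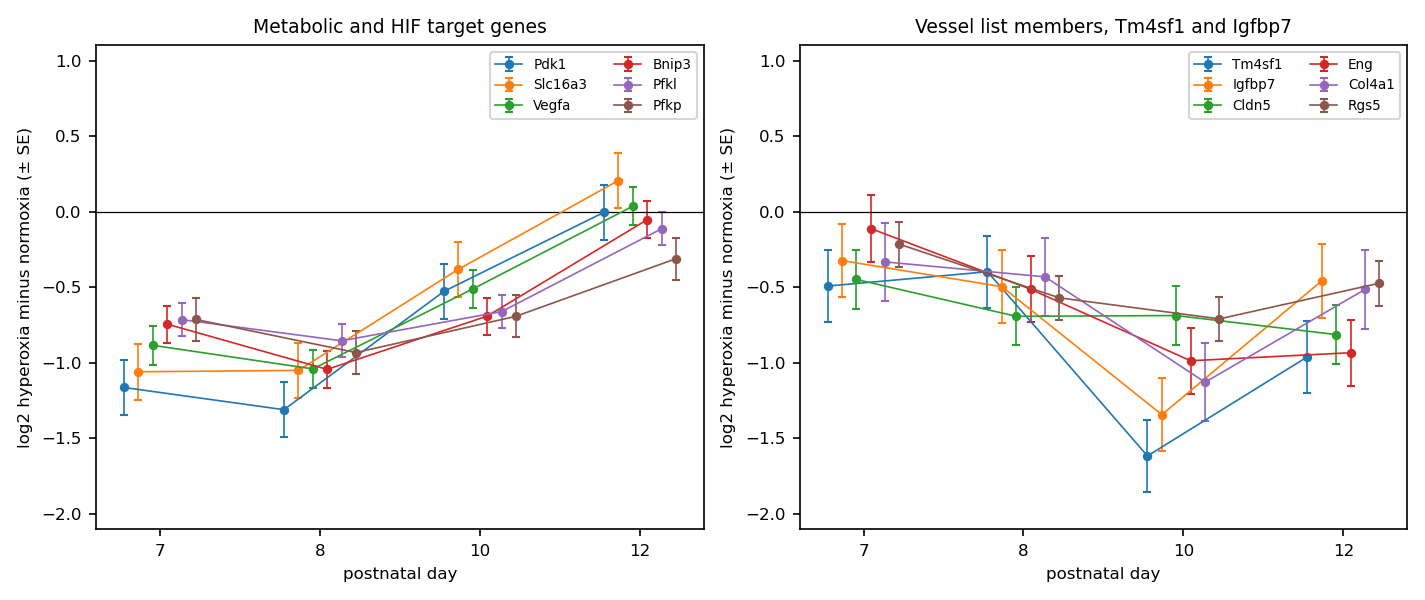
Log2 difference of hyperoxia minus room air at each postnatal day for 6 metabolic and HIF target genes (left) and 6 further genes, Cldn5, Eng, Col4a1 and Rgs5 from the vessel lists and Tm4sf1 and Igfbp7 (right); points are contrasts of 3 against 3 arrays and bars the standard error of the fit, with points set apart sideways for legibility. Pdk1 goes from -1.16 at day 7 and -1.31 at day 8 towards 0 at day 12, and Tm4sf1 is lowest at day 10, at -1.62.

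At day 10, after 72 hours, the largest falls were those of Tm4sf1, Mgp and Igfbp7, none of which stands in a vessel list. Tm4sf1, a membrane protein abundant in endothelium, fell by 1.62 ± 0.24 (adjusted p = 0.0237). Mgp, the matrix Gla protein, fell by 1.36 ± 0.24, and Igfbp7, a binding protein of vessel walls, by 1.34 ± 0.24 (adjusted p = 0.0411 for both). Mcm5, a subunit of the replication helicase, fell by 1.02 ± 0.16, and Gng11, Ostf1, Bnip3, Pfkl and Fam162a by 0.50 to 0.80. Uqcc2, an assembly factor of respiratory complex III, rose by 1.07 ± 0.19 (adjusted p = 0.0411). These 10 genes account for the 10 probe sets called, 1 higher and 9 lower. Without quantile normalization 10 probe sets were also called, 4 higher and 6 lower, of which 6 were among these 10.

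No member of the vessel lists passed over all probe sets at day 10, but 11 of 24 endothelial genes fell when adjusted over the list alone. The list mean was -0.49 (adjusted p = 5.29e-09; adjusted p = 0.156 with an estimated correlation), and 22 of 24 genes were negative, with Pecam1 at -1.19 ± 0.26 and Eng, a co-receptor of TGF-beta in endothelium, at -0.99 ± 0.22. Of 9 pericyte and smooth muscle genes, 3 fell adjusted over the list alone, among them Rgs5 at -0.71 ± 0.15 and Pdgfrb, the receptor that recruits pericytes, at -1.14 ± 0.27 (list mean -0.42, adjusted p = 0.00789; adjusted p = 0.287 with an estimated correlation). In the basement membrane list 4 of 13 fell adjusted over the list alone: Lamb1, Col4a1, Col4a2 and Nid2 (list mean -0.45, adjusted p = 0.000256; adjusted p = 0.0987 with an estimated correlation). The tip cell list also had 4 such members of 16 (list mean -0.39, adjusted p = 0.000769; adjusted p = 0.105 with an estimated correlation).

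The metabolic lists were still lower at day 10. Among HIF targets, 2 of 32 fell, Pfkl and Bnip3, and 10 did when adjusted over the list alone (list mean -0.29, adjusted p = 2.14e-08; adjusted p = 0.0459 with an estimated correlation). In the glycolysis list 1 of 15 fell and 6 did when adjusted over the list alone (list mean -0.26, adjusted p = 3.99e-06; adjusted p = 0.111 with an estimated correlation). Vegfa was at -0.51 ± 0.13 and did not pass (adjusted p = 0.157). Bnip3 and Pfkl were the genes called at days 7, 8 and 10.

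The limma fit gave 1729 probe sets at an unadjusted p under 0.05 at day 10. The count of 10 was 0 without hyperoxia replicate 1 (1163 at an unadjusted p under 0.05), 1 without room air replicate 1, 2 without hyperoxia replicate 3, 3 without hyperoxia replicate 2 and 3 without room air replicate 2. It was 3, none of them among the 10, with only the 6 arrays of day 10 in the fit, 16 with 1 probe set per gene, 17 with the higher floor, 18 without a filter and 22 without the 2 arrays farthest from their groups. The pericyte call ended without replicate 1 or 2 in all groups (adjusted p = 0.109 and 0.274), and the tip cell call without replicate 1 (adjusted p = 0.0734). Without a filter the angiogenic list was called at day 10 (mean -0.19, adjusted p = 0.0124).

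**Figure D2:**
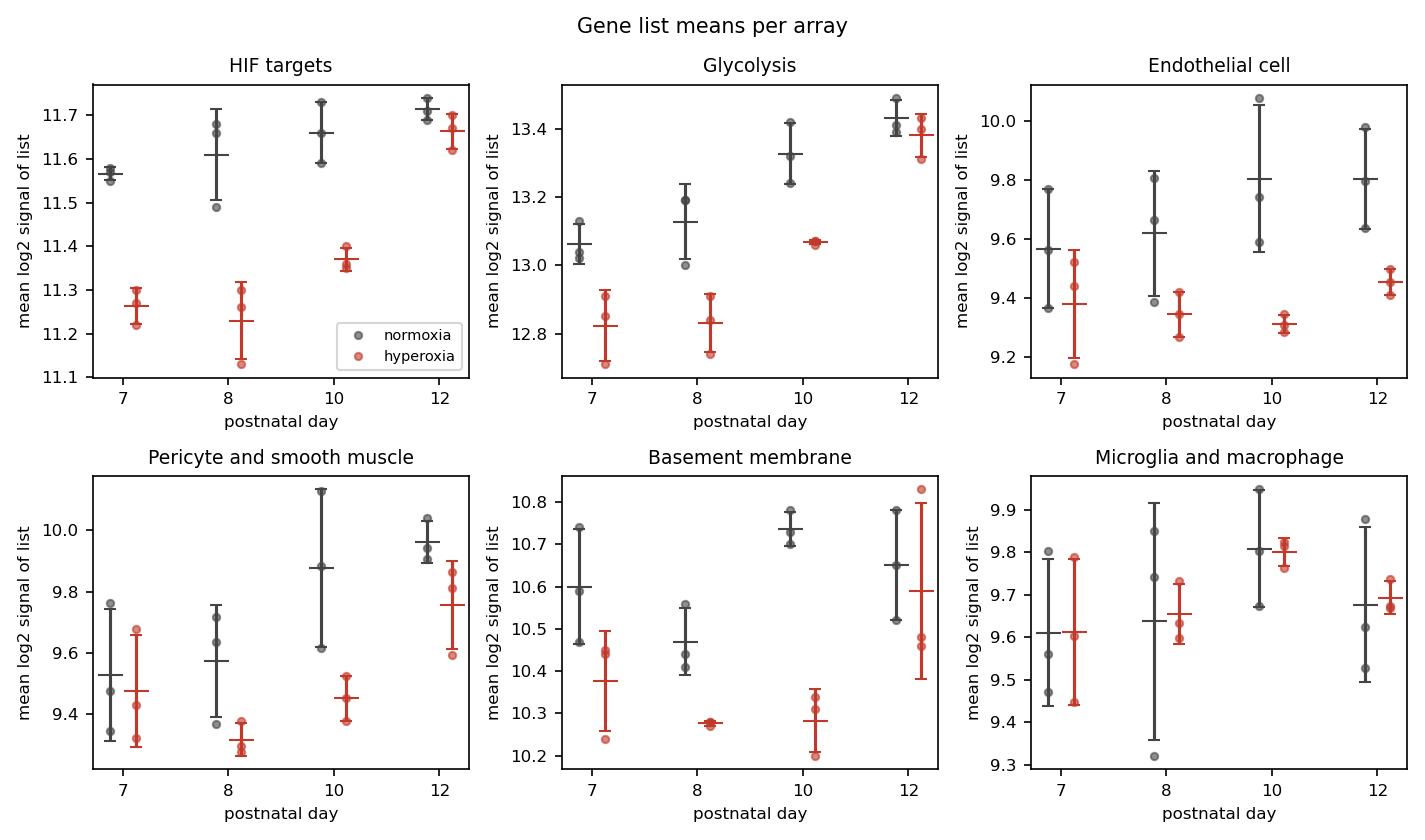
Mean log2 signal of the measured members of 6 gene lists on each array (points), with the group mean and SD (bars, n = 3), against postnatal day for room air and hyperoxia. The HIF target mean of the hyperoxia arrays lies between 11.13 and 11.4 up to day 10 and between 11.62 and 11.7 at day 12, beside 11.69 to 11.74 in room air at day 12.

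At day 12, after 120 hours, 2 probe sets were called, both lower. Naalad2, a peptidase of the N-acetylaspartylglutamate-cleaving family, fell by 1.38 ± 0.21, and Sema4b, a semaphorin, by 1.00 ± 0.15 (adjusted p = 0.0227 for both). The HIF targets stood close to their room air level, with a list mean of -0.05 and 0 of 32 passing (adjusted p = 0.795). Siglec1, a macrophage receptor, was at 1.87 ± 0.36, Dcaf4 at -0.97 ± 0.17 and Cfap298 at -0.58 ± 0.12, none of which passed.

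The endothelial list remained lower at day 12. Its mean was -0.35 (adjusted p = 4.94e-05; adjusted p = 0.555 with an estimated correlation), 0 of 24 members passed, and adjusted over the list alone 5 fell and 1 rose. Eng was at -0.93 ± 0.22, Cldn5 at -0.81 ± 0.19 and Aplnr, the apelin receptor, at -1.09 ± 0.30. The cell cycle list had a mean of -0.23, with Mcm6 at -1.09 ± 0.31 and 2 of 27 members passing adjusted over the list alone (adjusted p = 0.0325; adjusted p = 0.555 with an estimated correlation). Cholesterol synthesis genes had a mean of -0.16, with Mvk at -0.41 ± 0.15 (adjusted p = 0.0325; adjusted p = 0.555 with an estimated correlation).

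The 2 calls of the limma test, beside 1383 probe sets at an unadjusted p under 0.05, changed with the settings. With the replicate number as a block they became 4. They became 6 without hyperoxia replicate 1, 1, a different probe set, without room air replicate 1, and 0 without hyperoxia replicate 2, room air replicate 2 or hyperoxia replicate 3 (1025, 1248 and 1682 at an unadjusted p under 0.05). The cell cycle call ended without replicate 1 or 3 in all groups (adjusted p = 0.101 and 0.0753), on the deposited scaling (mean -0.14, adjusted p = 0.189), without a filter (adjusted p = 0.0799) and with the filter at the 50th percentile (adjusted p = 0.348). The cholesterol call ended without replicate 1 or 2 (adjusted p = 0.0982 and 0.236) and without the 2 arrays farthest from their groups (adjusted p = 0.267).

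Averaged over the 4 days, hyperoxia was associated with lower metabolic and endothelial transcripts. Ak4 fell by 0.88 ± 0.09 and Pdk1 by 0.75 ± 0.09 (adjusted p = 9.94e-06 and 9.41e-05); a brighter probe set of Pdk1 fell by 0.37 ± 0.07 (adjusted p = 0.0177). Bnip3 fell by 0.63 ± 0.06, Pfkp by 0.66 ± 0.07 and Pfkl by 0.59 ± 0.05. Vegfa fell by 0.60 ± 0.06 (adjusted p = 2.8e-05). Cd93, a receptor found on endothelium, and Tm4sf1 both fell by 0.87, and Cldn5 fell by 0.66 ± 0.10. Alas2, the erythroid enzyme of heme synthesis, fell by 1.08 ± 0.19 (adjusted p = 0.00697). Of 78 probe sets called, 75 were lower and 3 higher, standing for 57 and 3 named genes. The number higher was 14 without room air day 8 replicate 1, 11 without the 2 arrays farthest from their groups, and 0 in 8 of the other fits without 1 array. The rises were small: Tmem41b rose by 0.36 ± 0.08 and Naa40 by 0.26 ± 0.06. Naalad2, Ets1, Grhpr and the uncharacterised AU021092 and Gm13889 completed the largest falls, at 0.72 to 1.13. Ets1 also stands in the endothelial list, where it counts by a brighter probe set that was not called lower.

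By list, 10 of 32 HIF targets fell on average over the days, 19 adjusted over the list alone (mean -0.25, adjusted p = 5.91e-24; adjusted p = 0.000183 with an estimated correlation). Of 15 glycolysis genes 4 fell, 10 adjusted over the list alone, where 1 also rose (mean -0.21, adjusted p = 1.03e-14; adjusted p = 0.00735 with an estimated correlation). In the endothelial list 7 of 24 fell: Cldn5, Ramp2, Eng, Cd34, Aplnr, Sox17 and Sox18. Adjusted over the list alone 14 did (mean -0.33, adjusted p = 4.04e-18; adjusted p = 0.0183 with an estimated correlation). Of the tip cell list 2 of 16 fell, Cd34 and Col4a1, 5 adjusted over the list alone (mean -0.22, adjusted p = 7e-06; adjusted p = 0.0156 with an estimated correlation). Of the basement membrane list 1 of 13 fell, Col4a1, 6 adjusted over the list alone (mean -0.23, adjusted p = 7e-06; adjusted p = 0.0156 with an estimated correlation). In the pericyte list Rgs5 fell by 0.49 ± 0.07, the 1 of 9 members to pass, and 3 fell adjusted over the list alone (mean -0.23, adjusted p = 0.000106; adjusted p = 0.0679 with an estimated correlation). The microglia and macrophage list, also of cells that are not neurons, had a camera adjusted p no lower than 0.558 in any comparison.

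Further lists were called on average with smaller means and lost the call with an estimated correlation. These were the Müller glia list (mean -0.10, adjusted p = 0.00463; adjusted p = 0.211 with an estimated correlation) and the cell cycle list (mean -0.12, adjusted p = 0.00388; adjusted p = 0.211 with an estimated correlation). The angiogenic list had Vegfa as its 1 member to pass (mean -0.10, adjusted p = 0.0055; adjusted p = 0.126 with an estimated correlation). The pigment list had a mean of -0.22 (adjusted p = 0.0432; adjusted p = 0.665 with an estimated correlation), and the synaptic transmission list a mean of 0.06 with 16 of 22 positive (adjusted p = 0.0495; adjusted p = 0.214 with an estimated correlation). Without replicate 1 in all groups the cell cycle, angiogenic, pigment and synaptic calls ended (adjusted p = 0.279, 0.111, 0.354 and 0.583), without replicate 2 the pigment call did (adjusted p = 0.222), and without replicate 3 the Müller glia call did (adjusted p = 0.0618). With the filter at the 50th percentile the cell cycle mean was -0.04 and its call ended (adjusted p = 0.861), as did the angiogenic call (adjusted p = 0.197). The synaptic call ended under 7 further settings (adjusted p from 0.0517 to 0.287), the pigment call under 6 (adjusted p from 0.0522 to 0.326), and the angiogenic call with both tissue scores as covariates (adjusted p = 0.058).

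The hyperoxia effect was compared between days 12 and 7, and over all 4 days by an F test. Limma called 0 probe sets in the first, with 983 at an unadjusted p under 0.05, and 0 in the second, with 1039, against 792 expected without any change; the smallest adjusted p were 0.41 and 0.312. The genes with the lowest p were Vegfa, whose difference between the days was 0.92 ± 0.18, Slc16a3 at 1.26 ± 0.26, Ak4 at 0.98 ± 0.21, Polr3k, a subunit of RNA polymerase III, at -1.25 ± 0.25, and Sema4b at -1.05 ± 0.22, none of which passed. As lists, HIF targets differed by 0.26 (adjusted p = 2.85e-07; adjusted p = 0.0699 with an estimated correlation) and glycolysis genes by 0.19 (adjusted p = 0.000178; adjusted p = 0.478 with an estimated correlation), with 5 and 2 members higher adjusted over each list alone. The pigment list differed by 0.52 and cholesterol synthesis genes by -0.21 (adjusted p = 0.0434 for both; adjusted p = 0.742 with an estimated correlation for both). Both of these calls ended with the replicate number as a block (adjusted p = 0.0539 for both). The pigment difference was -0.08 without replicate 3 in all groups (adjusted p = 0.936), and the cholesterol call ended without replicate 1 or 2 (adjusted p = 0.0753 and 0.287). The cholesterol call also ended with the lens score (difference -0.19, adjusted p = 0.0724), with both scores (-0.22, adjusted p = 0.0632) and without the 2 arrays farthest from their groups (-0.18, adjusted p = 0.165), and the pigment call without a filter (0.48, adjusted p = 0.0661) and with the lens score (0.55, adjusted p = 0.0518). The angiogenic list was called on the deposited scaling (mean 0.22, adjusted p = 0.0286). Without hyperoxia day 12 replicate 1, the first comparison called 2 probe sets.

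From day 7 to day 12 in room air, photoreceptor genes rose and genes of dividing progenitors fell. Drd4, the dopamine D4 receptor, rose 48.9-fold (log2 5.61 ± 0.44, adjusted p = 1e-07), Guca1b, a guanylate cyclase activator of photoreceptors, 16.9-fold, the potassium channel Kcnj14 15.8-fold and the cone opsin Opn1mw 11.6-fold. Pdzph1 rose 8.9-fold, the rod exchanger Slc24a1 6.28-fold, the water channel Aqp4 6.13-fold, vitronectin (Vtn) 6.12-fold, rod transducin (Gnat1) 6.01-fold and Cav2 5.65-fold. The largest falls were those of Enc1, by 1.95 ± 0.23 on the log2 scale, and of Fabp7, Neurog2, Sox11, Slc27a2, Nts, Sox4, Grhl2, Pbk and Pax7, by 1.62 to 1.86. Fabp7, Neurog2, Sox11 and Sox4 are genes of neural progenitors and young neurons.

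In the room air lists, 14 of 21 rod genes rose, 17 adjusted over the list alone (mean 1.04, adjusted p = 9.17e-14). Of 11 cone genes 5 rose and 1 fell (mean 0.85, adjusted p = 0.00057), 9 of 22 synaptic genes rose, led by the GABA receptor subunit Gabrr2 at 2.37 ± 0.24 (mean 0.39, adjusted p = 0.00023), and 8 of 18 clock genes rose, among them Dbp at 1.80 ± 0.23 (mean 0.56, adjusted p = 1.75e-05). Of 14 progenitor genes 7 fell, with Ccnd1 at -1.24 ± 0.15 and Hes5 at -1.36 ± 0.20 (mean -0.72, adjusted p = 1.83e-07), and of 27 cell cycle genes 12 fell, with Ube2c at -1.38 ± 0.19 (mean -0.65, adjusted p = 5.1e-09). Adjusted over the list alone, 6 cone genes rose and 1 fell, 11 synaptic and 11 clock genes rose, and 9 progenitor and 15 cell cycle genes fell. These 6 calls held with an estimated correlation, at adjusted p of 0.0119, 0.0304, 0.0245, 0.0242, 0.0118 and 0.0133 in that order. Time of day, which the labels do not give, could not be separated from age for the clock genes or for others.

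Lists called in room air that lost the call were the Müller glia list, in which 7 of 16 rose and 1 fell, 9 and 2 adjusted over the list alone (mean 0.68, adjusted p = 4.12e-05; adjusted p = 0.055 with an estimated correlation), and the horizontal cell list, in which 3 of 5 rose (mean 0.63, adjusted p = 0.00511; adjusted p = 0.0826 with an estimated correlation). In the glycolysis list 7 of 15 rose, with the monocarboxylate transporter Slc16a1 at 1.87 ± 0.18 (mean 0.37, adjusted p = 0.00351; adjusted p = 0.276 with an estimated correlation). In the cholesterol list 3 of 19 rose, 6 adjusted over the list alone (mean 0.28, adjusted p = 0.00311; adjusted p = 0.131 with an estimated correlation). The pigment list was higher at day 12 by 0.67, with 1 of 11 members rising, Ttr (adjusted p = 0.0363; adjusted p = 0.672 with an estimated correlation), a call that ended without replicate 1 in all groups (adjusted p = 0.189) and with the filter at the 50th percentile (adjusted p = 0.1). The endothelial list, with a mean of 0.24, was called only without a filter (adjusted p = 0.00776), with the mean of all probe sets of a gene (adjusted p = 0.026), with the replicate block (adjusted p = 0.0455) and without replicate 2 or 3 (adjusted p = 0.0387 and 0.0497). In the lists named in every comparison other than HIF targets, Cd44 and Osmr rose by 1.22 and 1.15 and Nes fell by 0.87 among gliosis genes. Gsta4 rose by 0.91 among antioxidant genes, Eng and Esam rose by 0.80 and 0.68 among endothelial genes, and the growth factor Fgf1 rose 2.82-fold. Members of the HIF target list are left out here.

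Of 1955 probe sets called in room air, 1131 were higher and 824 lower. The count was 1193 without room air day 7 replicate 3, 923 with only the 6 arrays compared in the fit, 1300 with the pigment score as a covariate and 1265 with both tissue scores.

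**Figure D3:**
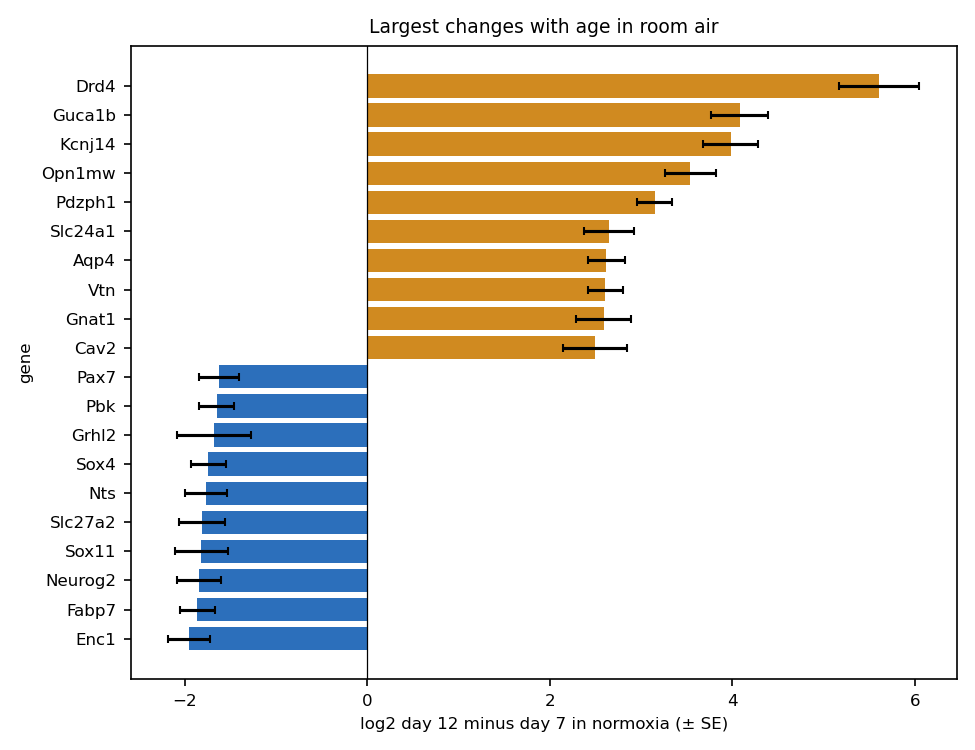
Log2 difference of day 12 minus day 7 in room air for the 10 largest rises and 10 largest falls chosen by rule; bars start at 0 and error bars are the standard error of the fit (3 against 3 arrays). The differences run from -1.95 for Enc1 to 5.61 for Drd4.

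Over the same interval in hyperoxia, 1993 probe sets were called, 942 higher and 1051 lower. With only the 6 arrays compared in the fit more were higher than lower, 337 and 260. Of the 1993, 668 were also higher in room air, against 67.3 expected for independent lists, and 488 were also lower, against 54.7; the comparisons share no array. Rod genes rose to a like extent, 14 of 21, 17 adjusted over the list alone (mean 1.00, adjusted p = 1.72e-15; adjusted p = 0.00531 with an estimated correlation). Cell cycle genes fell, 17 of 27, 19 adjusted over the list alone (mean -0.86, adjusted p = 4.55e-11; adjusted p = 0.00531 with an estimated correlation). Camera called HIF targets in hyperoxia (mean 0.41, adjusted p = 2.6e-06, or adjusted p = 0.023 with an estimated correlation). There 13 of 32 rose and 1 fell, 16 and 2 adjusted over the list alone. In room air camera did not call this list (mean 0.14, adjusted p = 0.5), but 6 of 32 rose and 1 fell. In limma on list means per array, HIF targets rose with age in both conditions. The rise was 0.144 in room air (adjusted p = 0.0219) and 0.405 in hyperoxia (adjusted p = 1.11e-06). Of 15 glycolysis genes 9 rose in hyperoxia, 11 adjusted over the list alone (mean 0.56, adjusted p = 1.78e-09, or adjusted p = 0.0141 with an estimated correlation).

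In the other lists called in hyperoxia between days 7 and 12, 9 of 16 Müller glia genes rose and 1 fell (mean 0.78, adjusted p = 1.05e-08), 8 of 22 synaptic genes rose (mean 0.50, adjusted p = 1.02e-07), 9 of 18 clock genes rose (mean 0.53, adjusted p = 4.23e-06) and 7 of 14 progenitor genes fell (mean -0.64, adjusted p = 2.25e-05). These held with an estimated correlation, at adjusted p of 0.0121, 0.00531, 0.0125 and 0.0125. Adjusted over the list alone, 12 Müller glia genes rose and 2 fell, 9 synaptic genes rose, 11 clock genes rose and 1 fell, and 7 progenitor genes fell. Cone genes, 5 of 11 rising and 1 falling (mean 0.56, adjusted p = 0.00649; adjusted p = 0.07 with an estimated correlation), horizontal cell genes, 2 of 5 rising (mean 0.57, adjusted p = 0.00439; adjusted p = 0.0683 with an estimated correlation), and astrocyte genes, 2 of 7 rising (mean 0.37, adjusted p = 0.0307; adjusted p = 0.206 with an estimated correlation), lost the call. The pigment list was higher by 1.19, with 4 of 11 rising (adjusted p = 5.51e-05; adjusted p = 0.327 with an estimated correlation). Without replicate 1 in all groups the cone and astrocyte calls ended (adjusted p = 0.0595 for both), and the astrocyte call also ended without replicate 3 (adjusted p = 0.175), with the pigment score (adjusted p = 0.41) or both scores (adjusted p = 0.426) as covariates and with the filter at the 50th percentile (adjusted p = 0.19). The count of 1993 was 597 with only the 6 arrays compared in the fit, 799 with the pigment score as a covariate and 668 with both tissue scores.

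Reactive gliosis, antioxidant, bipolar, amacrine, ganglion cell, microglia, myelin, p53, unfolded protein, heat shock, immediate early, interferon, inflammatory, complement, oxidative phosphorylation and apoptosis lists were called in none of the comparisons by camera. Their lowest adjusted p were 0.0817, 0.209, 0.126, 0.244, 0.0742, 0.558, 0.176, 0.448, 0.468, 0.18, 0.681, 0.181, 0.244, 0.328, 0.0709 and 0.196 in that order. In limma on list means per array, some passed with age. Bipolar, ganglion cell, gliosis and antioxidant means were higher at day 12 in room air (adjusted p 0.000336 to 0.0175) and hyperoxia (0.00195 to 0.019). Myelin was lower and interferon higher in room air (0.0346 and 0.0451), and inflammatory genes were higher in hyperoxia (0.00823). The reactive gliosis list was called at day 8 with the mean of all probe sets of a gene (mean -0.21, adjusted p = 0.0152) and for age in room air without replicate 3 (mean 0.40, adjusted p = 0.0435). Gfap, the filament of reactive glia, was at 0.24 ± 0.09 averaged over the days, and the glutathione transferase Gstm3 at 0.33 ± 0.09, neither of which passed. The cytokine receptor Osmr was at -0.40 ± 0.11 and did not pass.

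Transcripts of neighbouring tissues varied between arrays of the same group. The lens score ranged from 7.47 to 13.9 on the log2 scale over the 24 arrays, and the pooled SD within groups was 2.26. On the array with the lowest score, the first of room air day 12, 1 of the 16 lens genes lay above the median probe set of that array; on the array with the highest, 16 did. The pigment score ranged from 8.85 to 11.22, with 1 of 11 genes above the median on the lowest array and 8 on the highest. The arrays farthest from their group means were room air day 8 replicate 1 and hyperoxia day 12 replicate 2, with root mean square deviations of 0.302 and 0.298 beside a median of 0.233.

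**Figure D4:**
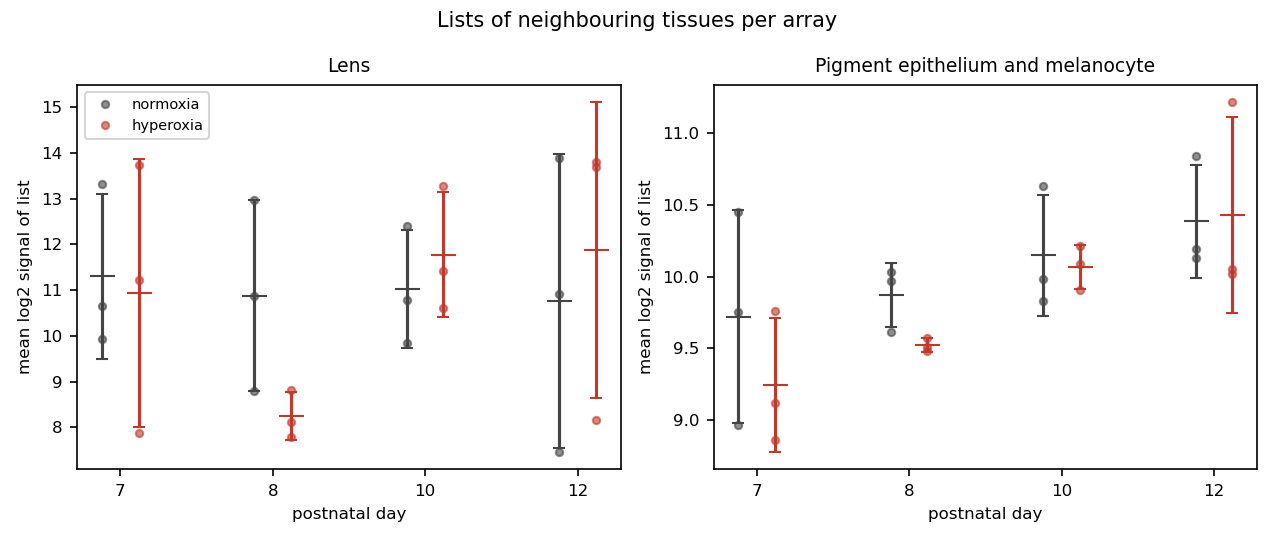
Mean log2 signal of the lens list (left) and of the pigment epithelium and melanocyte list (right) on each array (points), with the group mean and SD (bars, n = 3), against postnatal day. The lens score runs from 7.47 to 13.9, and at day 8 it is 7.80 to 8.83 under hyperoxia and 8.81 to 12.97 in room air.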

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

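In this part, the tests of the arrays farthest from their groups, of a lower yield of cells that are not neurons, of lens tissue, those using the lens and pigment scores, and those on list means per array, including the F test over the list scores, were chosen after the result or the data were seen; the day 12 minus day 7 contrasts and the other tests were planned. For the list means below, an explanation is argued against as the whole cause where the interval after the correction stays clear of 0, the mean stays past its bound by more than its standard error and the list stays called; this reading was also set after the values were seen, and a partial contribution stays open in each case.

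Lists singled out here are those that camera called, with its preset correlation, for the hyperoxia effect at day 12 minus that at day 7. With an estimated correlation all 4 calls ended: HIF targets (adjusted p = 0.0699 with an estimated correlation), glycolysis genes (adjusted p = 0.478 with an estimated correlation), and the pigment and cholesterol lists (adjusted p = 0.742 with an estimated correlation for both). On list means per array the same contrast had adjusted p of 0.0616, 0.39, 0.692 and 0.285 for HIF targets, glycolysis, pigment and cholesterol genes.

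HIF targets were lower under hyperoxia at days 7, 8 and 10 and close to their room air level at day 12, so that the effect differed by 0.26 between days 12 and 7. For this list the difference of the means per array among all 4 days had an adjusted p of 0.0384 in limma's F test over the list scores. Carry-over of lens and pigment tissue is argued against as the whole cause, since with both scores as covariates the list mean at day 8 was still -0.366 (95% interval -0.485 to -0.248). The quantile step of the normalization is argued against in the same way, the difference being 0.3 (0.159 to 0.441) on the deposited scaling. The deposited values had already been scaled to a common trimmed mean, so normalization as a whole was not tested. Without the 2 arrays farthest from their groups the difference was 0.243 (0.0877 to 0.398, bound 0.13, camera adjusted p = 2.99e-06). The mean at day 12 was then -0.0628 (-0.179 to 0.053). Of these arrays only hyperoxia day 12 replicate 2 enters the difference, and its list mean was 11.7 beside 11.67 and 11.62 in its group. Leaving it out could move the difference only little, so no further conclusion is drawn from this test. Age and duration of exposure stay open, as candidate explanations that the design does not separate.

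The endothelial list had a negative mean at all 4 days and was lower by 0.33 on average, while on list means per array only day 10 passed (adjusted p = 0.648, 0.342, 0.00931 and 0.176) and its camera calls at the single days ended with an estimated correlation (adjusted p = 0.294, 0.355, 0.156 and 0.555 with an estimated correlation). The pattern is weighed here although its difference between days 12 and 7, -0.16 (-0.568 to 0.245), was not past the threshold. A yield lowered equally for every cell that is not a neuron is argued against. The endothelial score fell by 0.333 more than the microglia and macrophage score (exact permutation within days, two-sided p = 2.5e-05). This rests on 1 comparison list. The pericyte, Müller glia and astrocyte scores shifted by -0.234, -0.1 and -0.0879 over the 4 days, and the myelin score by 0.0422. Their adjusted p in the same permutation were 0.018, 0.0673, 0.344 and 0.694. A lower yield of some of these cells therefore stays open. Carry-over of lens and pigment tissue with its vessels, as far as the scores measure it, is argued against as the whole cause: with both scores as covariates the mean was -0.302 (-0.449 to -0.156; camera adjusted p = 9.08e-16), 2.04 standard errors past the bound of -0.163, although the interval just includes that bound. Fewer endothelial cells and less transcript per endothelial cell were not tested against each other, and either may contribute to the -0.302.

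The lens list mean was lower by 2.64 under hyperoxia at day 8, a difference that did not pass in limma on list means per array (adjusted p = 0.429). Uneven carry-over of lens at dissection is a candidate explanation: within groups, the lens membrane and filament genes Mip and Bfsp1 followed the 14 measured crystallins over the 24 arrays (Pearson r = 0.958, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.956, permutation p = 2e-05; r = 0.949 without the 2 arrays farthest from the median). Of the 16 measured lens genes, 1 stands in another list. An effect of hyperoxia on lens transcripts stays open: the mean shift at the other 3 days was 0.507, and it differed from that at day 8 by 3.14 with a 95% interval of -1.37 to 7.66. The bound written for this test left out the error of the day 8 shift itself, and over the 4 days the score did not differ between conditions past the threshold (exact permutation p = 0.759).

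The difference between days 12 and 7 was 0.192 for glycolysis genes. It was 0.522 for the pigment list and -0.208 for cholesterol synthesis genes.

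Other splits of the same arrays were refitted for each count of called probe sets. For the average over the 4 days, 1 of 100 splits within days, the real one, gave 78 or more, and the highest other gave 1. A random division of the arrays is therefore an unlikely source of the 78, but is not excluded. For the F test over the days and for the day 12 minus day 7 difference, where 0 were called, all 100 of 100 splits gave as many, with up to 6 and 9. These splits within days ignored any pairing by number. The comparisons of 3 against 3 arrays allow only 10 splits, too few for a share under 0.05. Their real counts and highest others were 10 and 1 at day 7, 13 and 0 at day 8, 10 and 0 at day 10, 2 and 4 at day 12, 1955 and 0 for age in room air, and 1993 and 45 for age in hyperoxia; as many as the real count came from 1, 1, 1, 2, 1 and 1 of the 10 splits. If the numbers pair the arrays at day 12 and for age in hyperoxia, 4 splits part all 3 pairs. Among these the real count and the highest other were 2 and 0 at day 12 and 1993 and 0 for age in hyperoxia. The splits with 4 and 45 calls do not part all pairs, so they drop out only through a pairing that was not tested.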

How the results depend on the processing

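The lens, pigment and deviant-array settings in this part were chosen after the data were seen; the others were planned. Values are counts of called probe sets unless stated, and the cause of a change was not tested. The number called at day 7 was 18 with the replicate number as a block, 17 with an intensity trend and robust prior, and 0 with only the groups compared in the fit. At day 8 it was 0 with only those groups and 8 with both tissue scores. At day 10 it was 17 with the floor at the 40th percentile, 18 without a filter, 34 with the replicate block, 16 with 1 probe set per gene, 3 with only the groups compared and 22 without the 2 deviant arrays. At day 12 it was 0 on the deposited scaling, without a filter, with the filter at the 50th percentile, with the trend and robust prior, with only the groups compared and without the deviant arrays (limma; 1390, 1747, 1039, 1361, 876 and 1103 at an unadjusted p under 0.05). There it was 1 with the floor at the 10th percentile, 9 with that at the 40th, none of them shared with the 2 called, and 4 with the block. For age it was 923 in room air and 597 in hyperoxia with only the groups compared, 1300 and 799 with the pigment score, and 1265 and 668 with both scores. The day 12 minus day 7 difference gave 1 without a filter and 1 with the block, and the F test 2 without a filter. The average over the days stayed within 1.5 times of 78 under each setting run.

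Leaving out 1 array at a time gave 1 to 10 at day 7, 7 to 11 at day 8, 0 to 7 at day 10, 0 to 6 at day 12, 56 to 86 for the average, 1193 to 1809 for age in room air, 1395 to 1744 for age in hyperoxia, 0 to 2 for the day 12 minus day 7 difference and 0 to 0 for the F test. A lone pair of arrays is then assumed to vary like the other groups.

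Same-day arrays with a shared number correlated with r from -0.31 to 0.445, over 0.1 in 5 of 12 pairs, and 15 of 24 arrays correlated best with their own number, a hint from the data and not the design. Where a pairing was taken as possible, the block moved the count at day 12 from 2 to 4 and left that for age in hyperoxia within 1.5 times. At days 7 and 10, where it was not, the block moved the count from 10 to 18 and from 10 to 34. Among list tests it changed 5 of 89 and among named genes 14 of 313, 13 of them newly past the threshold. With an estimated correlation 38 of 89 list tests lost the call, and with the deposited scaling 3 did. Of 313 named values, the deposited scaling ended 10 calls and the 40th percentile floor 14. No named gene turned its direction while called. The pigment list, called at 0.522 for the day 12 minus day 7 difference, was at -0.0795 without replicate 3, where it was not called. The median difference of all probe sets was under 0.1 in size for every comparison under both scalings. Signals near the floor limit what can be seen of dim genes.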

Other observations

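In this part, the settings of the slope test below, the comparison of lists with their age change and the exact tests of list means per array were chosen after the data were seen; the slope test itself was planned.

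Tested on their own with exact permutation within days, the list means per array of 7 of 35 lists differed between conditions over the 4 days. These were HIF targets (adjusted p = 0.000875), glycolysis (0.00109), tip cell (0.00131), endothelial (0.00153), basement membrane (0.00692), pericyte (0.018) and angiogenic genes (0.0453), all with lower means under hyperoxia. The cone list had means of 0.08, 0.11, -0.20 and -0.22 at days 7, 8, 10 and 12, and the difference among the days did not pass in limma's F test over the list scores (adjusted p = 0.316).

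Differences at day 10 and day 12 correlated across probe sets with r of 0.496, although no probe set was called at both and the comparisons share no array; probe sets are not independent replicates. The correlation was -0.0479 between days 7 and 8, where the called probe sets overlap.

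A hypothesis was that hyperoxia delays the change that the retina undergoes between days 7 and 12 in room air. The hyperoxia difference at each day was regressed across 15838 probe sets on an age difference taken from room air arrays of other days. The mean slope was -0.14 (exact permutation within days, two-sided p = 0.00329), with slopes of -0.032, -0.0228, -0.257 and -0.248 at days 7, 8, 10 and 12. The permutation ignored any pairing by number, at day 12 and at the other days. The mean slope was -0.129 with the lens and pigment scores removed (exact p = 0.0107) and -0.164 on the deposited scaling (exact p = 0.00192). Without the vessel, HIF target and glycolysis lists it was -0.137 (exact p = 0.00394). That setting kept 15694 of the 15838 probe sets. It removed only the listed genes and left in any other gene that changes with vessels or oxygen. Without the 2 arrays farthest from their groups the mean slope was -0.122, with slopes of -0.0122, -0.0739, -0.257 and -0.145 at days 7, 8, 10 and 12. No exact test was run for this setting. Of the 11 lists called with age in room air, 9 shifted against their age change at days 10 and 12, and 2 shifted with it. The room air day 12 arrays enter the age change and the shift with opposite signs, and the lists were selected by that age change. Both favour shifts against the age change, so no conclusion on a delay is drawn from this count. Among the 9, intervals were clear of 0 for 3: cone genes at -0.21 (95% interval -0.348 to -0.0644; adjusted p = 0.055), glycolysis at -0.15 (-0.247 to -0.0601; adjusted p = 0.066) and cholesterol synthesis at -0.13 (-0.208 to -0.0463; adjusted p = 0.066), all of which rose with age. Progenitor genes, which fell with age, were at 0.08 (-0.0202 to 0.179). The 2 others were cell cycle and synaptic genes. Cell cycle genes, which fell with age, were lower still under hyperoxia, by 0.22 on average over the 2 days (95% interval -0.342 to -0.0985; exact permutation within days, p = 0.01, adjusted p = 0.055 over the 11 lists). Synaptic genes, which rose with age, had a mean of 0.11 (0.0269 to 0.183; adjusted p = 0.066). The cell cycle mean over these days was -0.0902 (-0.209 to 0.0284) on the deposited scaling and -0.109 (-0.22 to 0.00223) with the filter at the 50th percentile, where 10 of its genes were measured. It was -0.187, -0.216 and -0.213 without a filter, with both tissue scores and without the 2 arrays farthest from their groups, with intervals under 0. Whether a delay includes the cell cycle genes cannot be told apart, because the interval depends on the scaling and the filter, and a delay of the program stays open; loss of vessels, body growth and litter were not tested.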
